A study of Homo sapiens with 5 samples.

How the data were processed

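The data are small RNA reads from Argonaute HITS-CLIP, in which proteins are crosslinked to RNA in intact cells with ultraviolet light, Argonaute is immunoprecipitated and the RNA it holds is sequenced. Per the labels' protocols, lysates were treated with RNase, Argonaute-RNA complexes were cut from a gel, and linkers were ligated to the RNA. The labels name 2 antibody clones, 1 in the protocol (2A8) and another in the sample characteristics (4F9), and which of them was used is not settled here. The 5 libraries come from HMLE cells, an immortalised human mammary epithelial line. Of these, 2 were untreated (HMLE replicates 1 and 5) and 3 were treated with TGF-β at 2.5 ng/mL for 18 days (MesHMLE replicates 3, 4 and 5). Groups were taken from the sample titles. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

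The deposited values are raw read counts, 1 file per library, with 1 row per miRBase mature accession and genomic copy. The submitters' processing notes name bcl2fastq, cutadapt 2.8, UMI-tools, BWA 0.7.17, edgeR 3.34.0 and the genome build hg19, without the role of each. The files' names add that reads were trimmed, aligned, sorted and deduplicated before counting. The counting tool and the miRBase release are not given in the sources used here. Deduplication by molecular tags removes PCR copies, and how far it also merged distinct molecules of very abundant miRNAs is not known. Each file holds 2104 rows for 1919 accessions. Of these accessions, 144 are split over several genomic copies, in 329 rows. A further 5 rows name no feature and were kept out of library sizes and tests. The largest of them, for reads of too low alignment quality, held 45.8% and 57.6% of all counts in HMLE replicates 1 and 5, and 59.7%, 40.5% and 56.3% in MesHMLE replicates 3, 4 and 5. Reads outside any feature made up 4.69% to 11.7%. Reads that fit several loci equally well are usually given a low alignment quality, so the level of an accession with several copies is uncertain.

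The files give accessions, and no table used here pairs them with miRNA names. No name was assigned, and at most 2 accessions that rose and 2 that fell are printed. The 18 lists of miRNA names fixed in advance, the comparison of 5p with 3p arms and the split by miRNA number all need names and were not run. The split was replaced by one on the accession number, at 5000, since miRBase accessions were given out in rising order as sequences were registered. Apart from this and the additions named below, the design, the alternatives and the rule for named entries were set before the data were examined. That rule takes the called entries with the largest fold changes whose 3 MesHMLE values all lie on one side of both HMLE values, and the most abundant entries. Here the first 2 of each kind are given.

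Counts were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr (minimum count 10), TMM factors and the robust quasi-likelihood test of MesHMLE against HMLE over all 5 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values were computed with edgeR's cpm function on TMM-scaled library sizes. Counts were also simulated with the abundances and depths of these 401 tested entries and the trend of their dispersions. In each of 5 simulations 200 entries were changed, and 97.4% of 16-fold falls and 97.0% of 16-fold rises were called. For 4-fold changes the shares were 50.8% and 40.4%, and for 2-fold changes 17.7% and 7.53%. Of 444 calls, 11 were false, and 0 calls were made over the 5 simulations with nothing changed. The trend leaves out the extra spread of single entries. Changing 200 of 401 entries also eases the Benjamini-Hochberg threshold, so the shares called may be too high for these libraries. With counts drawn from the fitted model, few calls are to be expected when nothing is changed. Group means of shares were compared with a two-sided exact permutation test over the 10 splits of 2 against 3 libraries, whose smallest p is 0.2. It was planned only for shares of the fixed lists, and its use on the shares given here was an addition. Detection means at least 10 counts, with copies of an accession summed, and shares carry 95% Wilson intervals. Intervals and floors cover counting error only. Alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1), other filters, leaving out the 10 most abundant entries and leaving out each library. Chosen after seeing the data were a block for depth (above or below 1000000 counts), thinning to the smallest library for the test of treatment (for detection it was set in advance), summed copies, leaving out MesHMLE replicates 3 and 5 together, and, for detection, single copies and a boundary at 10000.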

Results

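Argonaute-bound small RNA was profiled in untreated HMLE cells and in HMLE cells held in TGF-β, a cytokine that drives epithelial cells towards a mesenchymal state. The series addressed which annotated human miRNAs are held by Argonaute, and its design compared the miRNA profile of the untreated cells (2 libraries) with that of the treated cells, called MesHMLE (3 libraries). Reads assigned to miRNA entries numbered 1495769 and 445755 in HMLE replicates 1 and 5, and 170833, 2457615 and 120256 in MesHMLE replicates 3, 4 and 5. An entry is a mature accession at a single genomic copy. A count of 0 allowed up to 1.51 and 8.18 TMM-scaled CPM in HMLE replicates 1 and 5 and 23.4, 0.724 and 34.8 CPM in MesHMLE replicates 3, 4 and 5, so low entries were measured far less precisely in MesHMLE replicates 3 and 5.

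MIMAT0000076_1 was the most abundant entry in every library. It took 12.8% ± 1.89 (SD, n = 2) of the miRNA counts in HMLE and 23.9% ± 12.3 (SD, n = 3) in MesHMLE, where it ranged from 9.67% in replicate 4 to 31.5% in replicate 3. MIMAT0000098_1 came next by mean CPM over the 5 libraries. It ranked 2 in MesHMLE replicates 3 and 5 but 3 in MesHMLE replicate 4, and 4 and 7 in HMLE replicates 1 and 5. It took 3.23% ± 0.337 (SD, n = 2) in HMLE and 10.5% ± 5.5 (SD, n = 3) in MesHMLE, and its share was higher in 3 of 3 treated libraries. After TMM scaling it was lower in MesHMLE replicate 4, at 28498 CPM, than in HMLE replicate 5, at 36385 CPM. Neither difference held up against the spread between libraries. Two-sided exact permutation p-values over the 10 splits were 0.6 for MIMAT0000076_1 and 0.2, the smallest possible, for MIMAT0000098_1, with adjusted values of 0.771 and 0.6 over the 9 shares compared. The edgeR quasi-likelihood test gave MIMAT0000098_1 a log2 fold change of 2.07 (SE 0.88, adjusted p = 0.352) and MIMAT0000076_1 one of 1.22 (SE 0.96, adjusted p = 0.705).

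The 10 most abundant entries of each library together held 41.2% and 58.5% of the counts in HMLE replicates 1 and 5. In MesHMLE replicates 3, 4 and 5 they held 64.2%, 38.3% and 67.7%. The group means were 49.8% ± 12.2 (SD, n = 2) and 56.7% ± 16.1 (SD, n = 3), a difference smaller than the spread within either group (two-sided exact permutation p = 0.6, adjusted 0.771), which turned to -1.77 percentage points without HMLE replicate 1. In both groups the deepest library had the lowest share.

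**Figure D1:**
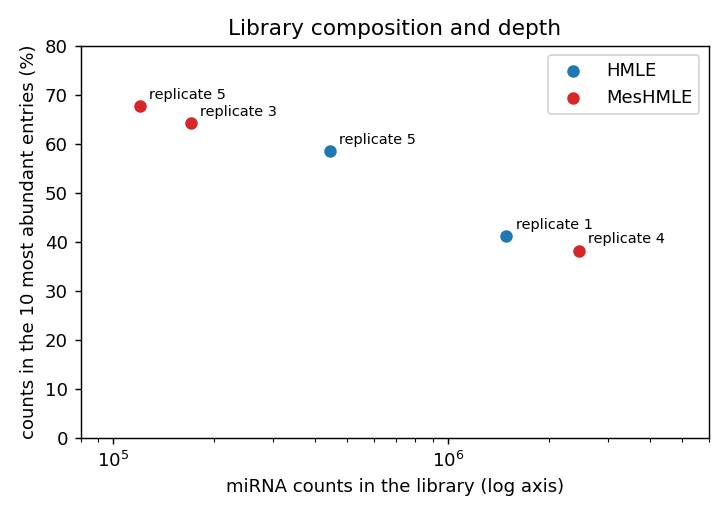
Percentage of each library's miRNA counts held by its 10 most abundant entries (y axis) against its total miRNA counts (x axis, log scale), 1 point per library, coloured by group. The deep libraries, HMLE replicate 1 and MesHMLE replicate 4, lie at 41.2% and 38.3%, and the other 3 between 58.5% and 67.7%.

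The comparison of treated with untreated cells called more entries as falling than as rising in the Argonaute-bound pool. Among 401 entries tested, 13 fell and 2 rose in MesHMLE (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 in the same test, 32 fell and 17 rose. The median log2 fold change of all tested entries was 0.03. The simulations also called a smaller share of rises than of falls at 2-fold and 4-fold. Their fitted log2 changes leaned towards falls, at -1.33 for 2-fold falls and 0.79 for 2-fold rises. At 4-fold they were -2.27 and 1.99. The difference in shares may therefore not apply to these libraries, where the median was 0.03. The 13 that fell together held 12.3% ± 4.12 (SD, n = 2) of the miRNA counts in HMLE and 1.05% ± 0.626 (SD, n = 3) in MesHMLE. The 2 that rose went from 0.235% ± 0.174 (SD, n = 2) to 1.26% ± 0.731 (SD, n = 3). As these entries were selected by the same test, the shares are not independent evidence. For both shares every treated library lay on one side of both untreated ones (two-sided exact permutation p = 0.2, the smallest possible, adjusted 0.6).

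MIMAT0001536_1 had the largest fitted fall of the 13. It stood at 393 ± 181 CPM (SD, n = 2) in HMLE and 3.16 ± 4.10 CPM (SD, n = 3) in MesHMLE, a log2 fold change of -7.37 (SE 1.04, edgeR adjusted p = 0.00447). Its raw counts were 524 and 191 in the untreated libraries and 1, 7 and 0 in the treated ones. MIMAT0004987_1 fell from 225 ± 67.9 CPM (SD, n = 2) to 1.45 ± 2.51 CPM (SD, n = 3), a log2 fold change of -6.07 (SE 0.98, edgeR adjusted p = 0.0106). It had 541 and 65 counts in HMLE, 18 in MesHMLE replicate 4 and 0 in MesHMLE replicates 3 and 5. By the ratio of the group means, with zeros taken as 0 CPM, the order was the other way (155-fold for MIMAT0004987_1 against 124-fold for MIMAT0001536_1). A count of 0 allowed up to 23.4 and 34.8 CPM in MesHMLE replicates 3 and 5, so which of them fell further is not settled. The fitted log2 fold change of MIMAT0004987_1 was -10.34 without MesHMLE replicate 4. There the treated libraries that remain are at 0 and show only that it was at least 7.75-fold lower, at the mean of their floors of 3 counts per library. The fitted falls of all 13 entries spanned 4.55-fold to 166-fold. In 9 of them the fitted fall was over 16-fold and in the other 4 it was under 6-fold. Of the 13, 6 had 0 counts in MesHMLE replicate 5, where 0 allowed up to 34.8 CPM. These 6 are all among the 9 with falls over 16-fold, so the size of their falls is uncertain. The fallen entries included abundant ones, with 7 above 1000 CPM in HMLE on average.

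MIMAT0000265_1 had the larger rise of the 2, from 211 ± 47.2 CPM (SD, n = 2) in HMLE to 2967 ± 1344 CPM (SD, n = 3) in MesHMLE, a log2 fold change of 3.81 (SE 0.53, edgeR adjusted p = 0.00447). The other riser, MIMAT0002809_1, went from 1818 ± 903 CPM (SD, n = 2) to 8787 ± 2171 CPM (SD, n = 3), a log2 fold change of 2.27 (SE 0.48, edgeR adjusted p = 0.0338). Without HMLE replicate 5 or without MesHMLE replicate 3, MIMAT0002809_1 no longer passed the threshold (edgeR adjusted p = 0.253 and 0.164), and 1 entry rose in each case. An entry with a larger fitted log2 fold change of 4.02 (SE 0.95) missed the threshold (edgeR adjusted p = 0.0507). Each of the 15 called entries had all 3 treated libraries on one side of both untreated libraries, as did 30.7% of all tested entries, where chance gives 20%. None of the 15 belonged to an accession with several genomic copies.

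**Figure D2:**
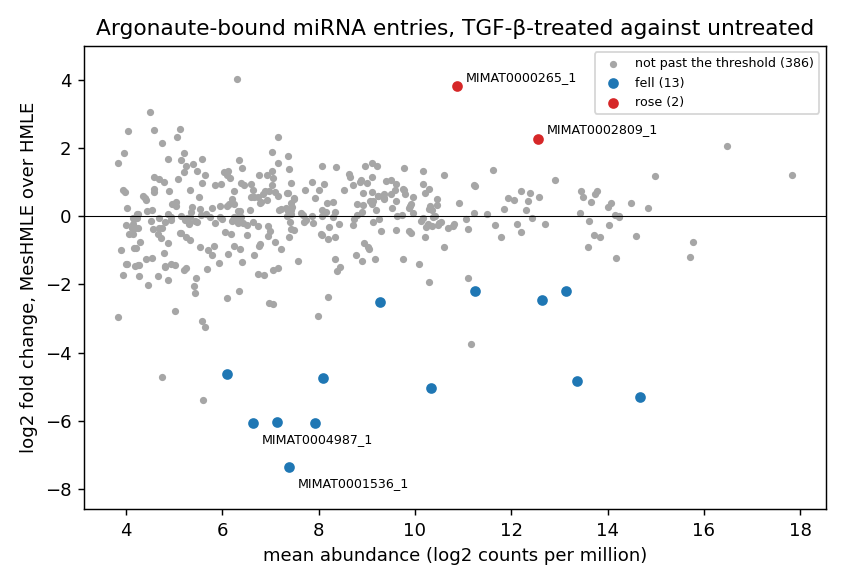
Log2 fold change of MesHMLE over HMLE (y axis) against mean abundance in log2 CPM (x axis) for the 401 tested entries, 1 point per entry. The 13 that fell are blue, the 2 that rose are red, and the 4 named ones carry their accession.

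**Figure D3:**
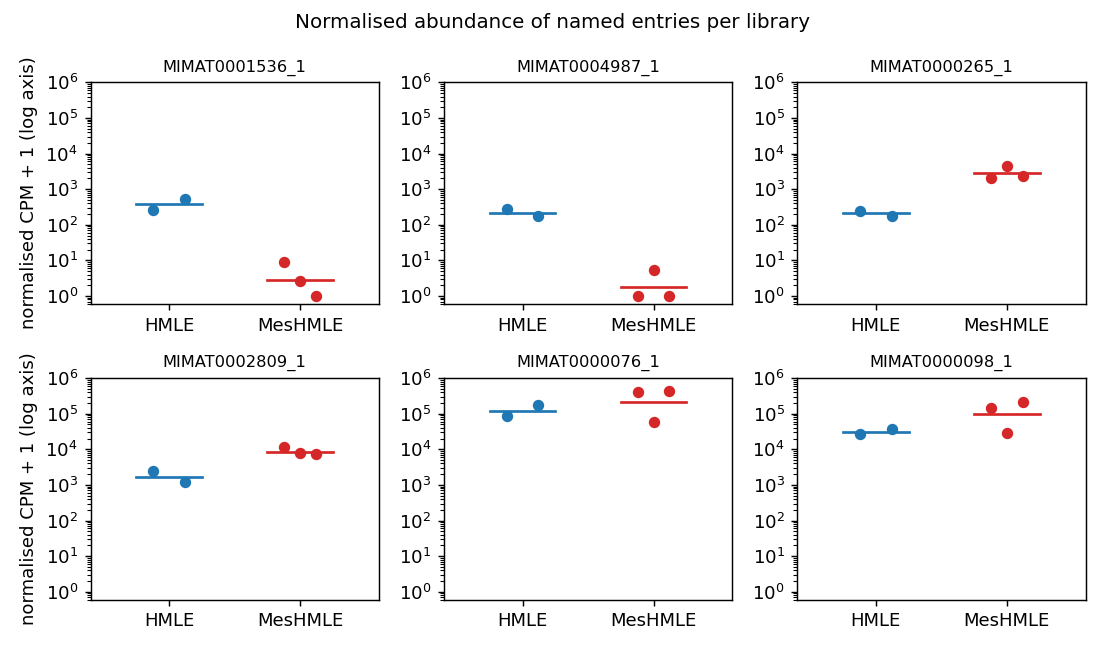
TMM-normalised CPM plus 1 (y axis, log scale) of 6 entries in each library, by group, with 1 point per library and a line at the mean of the log values. MIMAT0001536_1 and MIMAT0004987_1 were lower in all 3 MesHMLE libraries than in both HMLE libraries, MIMAT0000265_1 and MIMAT0002809_1 were higher, and the 2 most abundant entries did not pass the test.

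Depth split both groups, with HMLE replicate 1 and MesHMLE replicate 4 above 1000000 counts and the other 3 libraries below. The median change of the 13 fallen entries on the log2(CPM + 1) scale was -4.59 between the deep libraries and -5.60 between the shallow ones (2 MesHMLE against 1 HMLE), both conditioned on the entries having been called from these libraries. Zeros entered as 0 CPM, though 0 allowed up to 23.4 and 34.8 CPM in MesHMLE replicates 3 and 5. Of the 13, 6 had 0 counts in MesHMLE replicate 5. The size of any fall between the shallow libraries is uncertain where counts were 0. Over all 401 tested entries, the changes between the deep libraries and those between the shallow libraries, which share no library, correlated weakly (Pearson r = 0.163, Spearman rho = 0.0797, across entries). Of the 20 entries with the largest fall between the deep libraries, 12 were also lower in MesHMLE in the shallow ones, where 50.6% of all tested entries were lower. Their median there was -5.18, against -0.05 for all entries. Of the 20 with the largest rise between the deep libraries, 14 were higher in the shallow ones, with a median of 0.74. With depth as a block, 13 entries fell and 2 rose (edgeR quasi-likelihood test), of which 11 and 2 were among the 15. Without HMLE replicate 1 the count that fell was 21. Across the tested entries, log2 CPM correlated with Pearson r = 0.883 between the HMLE libraries and 0.846 to 0.876 within MesHMLE, against 0.708 to 0.884 between the groups. Spearman rho was 0.836 between the HMLE libraries and 0.845 to 0.916 within MesHMLE. With the MesHMLE libraries it was 0.859 to 0.872 for HMLE replicate 1 and 0.705 to 0.829 for HMLE replicate 5. By rank, HMLE replicate 1 was thus closer to each MesHMLE library than to HMLE replicate 5. Entries are not independent replicates.

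Annotated miRNAs were unevenly represented in the Argonaute-bound pool by the age of their registration. Of 696 accessions numbered under 5000, 167 reached 10 counts in all 5 libraries, or 23.99% (95% Wilson interval 20.97% to 27.3%). Of 1223 accessions numbered 5000 or above, 16 did, or 1.31% (0.807% to 2.11%), and 2.21% without MesHMLE replicate 5, the shallowest library. No library reached 10 counts for 314 of the earlier accessions (45.1%) and for 999 of the later ones (81.7%, 79.4% to 83.8%), and 700 of the later ones had 0 counts in all 5 libraries. The later accessions took 1.59% and 1.22% of the miRNA counts in HMLE replicates 1 and 5, and 0.824%, 2.16% and 0.694% in MesHMLE replicates 3, 4 and 5. Detection followed depth. In MesHMLE replicate 4, the deepest library, 52.2% of the earlier and 17.3% of the later accessions were detected, against 26.7% and 1.55% in MesHMLE replicate 5, the shallowest. The earlier accessions were detected more often in each of the 5 libraries. Accessions with no counts were not detected among the assigned reads at this depth in these cells. Reads of too low alignment quality, 40.5% to 59.7% of all counts per library, were not assigned to any accession. No library of total RNA was analysed here to set the bound pool against. Among the tested entries 308 were numbered under 5000 and 93 at 5000 or above, and 14 and 1 of them were called.

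**Figure D4:**
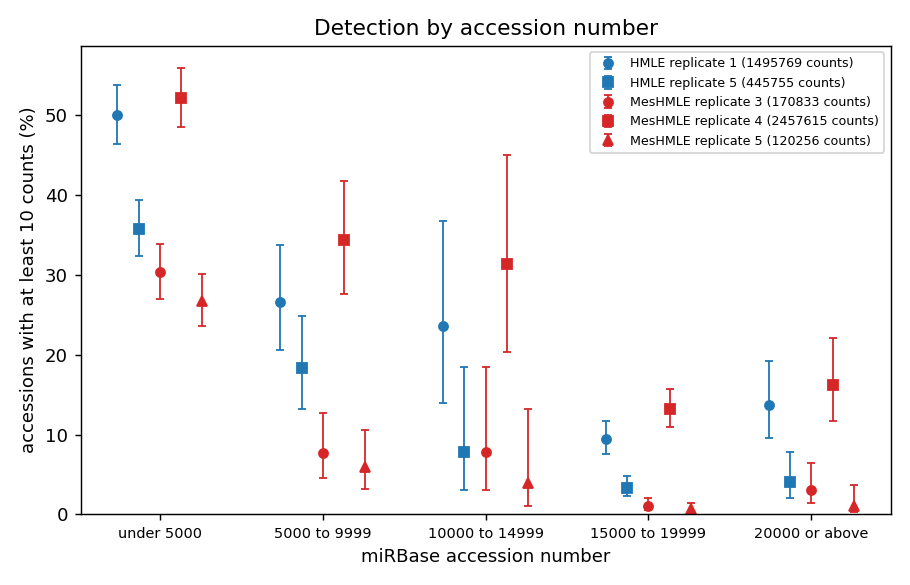
Percentage of accessions with at least 10 counts (y axis) by miRBase accession number (x axis), 1 point per library with its 95% Wilson interval, HMLE in blue and MesHMLE in red. In each library the share was highest for accessions under 5000, from 26.7% to 52.2%.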

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

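No paired analysis was possible because the groups share only 1 replicate number. Not run, for want of miRNA names, were the settings on fixed lists, arms, summed arms and entries described as other RNA classes. In all 17 alternatives the 15 called entries that entered the fit kept their direction. MIMAT0001536_1, MIMAT0004987_1 and MIMAT0000265_1 passed the threshold in 17 of 17 and MIMAT0002809_1 in 15 of 17, with adjusted p from 0.00108 to 0.253. The log2 fold change of MIMAT0004987_1 went from -6.07 to -10.34 without MesHMLE replicate 4, where its remaining treated libraries are at 0 and the fitted value is no bound. The 13 that fell became 21 with DESeq2, 20 without a low-count filter (1038 entries tested) and 7 in a single thinning to the smallest library, or 3 to 15 over 20 thinnings, where 1 or 2 rose. Leaving out each library gave 9 to 21 that fell (21 without HMLE replicate 1, 9 without MesHMLE replicate 3) and 1 to 3 that rose (1 without HMLE replicate 5 or MesHMLE replicate 3). Why these numbers changed was not tested. Under the other scalings 12 to 15 fell and 2 or 3 rose. RLE moved the median log2 fold change of all entries from 0.03 to -0.15, far less than the called changes. Without MesHMLE replicates 3 and 5, 12 fell and 3 rose, of which 8 and 2 were among the 15, with the lone MesHMLE library assumed to vary like HMLE. The difference in the share of the 10 most abundant entries, 6.89 percentage points, was 0.299 for the top 50 and ran from -1.77 (without HMLE replicate 1) to 15.5 and 16.1 (without HMLE replicate 5 or MesHMLE replicate 4). Detection in all libraries moved with the count minimum by construction, to 37.8% and 4.33% of earlier and later accessions at 1 count and to 14.7% and 0.327% at 50 counts. It was 20.4% and 0.899% after thinning, 20.3% and 0.664% with the boundary at 10000, and 23.99% to 27.7% and 1.31% to 2.21% with each library left out, highest without MesHMLE replicate 5. What depth alone limits was not separated from the spread between libraries or their number.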

Other observations

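The tests of copy ratios, of deduplication, of treatment as the source of the composition and of depth (thinning and block) were chosen after the results they bear on were seen, and the thinning was repeated 20 times after a single one was seen. The tests of scaling and of other splits of the libraries were set before their results. Accessions with several genomic copies were described by how their counts split over the copies. These accessions held 1.56% to 4.27% of the miRNA counts, highest in MesHMLE replicate 4. Reads that fit several copies equally well are usually given a low alignment quality. Such reads may be missing from this share and from the ratios below. In 18 of them at least 2 copies averaged 10 counts, giving 20 ratios between copies. None of the 20 passed the threshold for a difference between MesHMLE and HMLE (limma on log2 ratios with a pseudocount of 0.5, 0 calls, smallest adjusted p = 0.45, 1 at an unadjusted p under 0.05), and no other tool was run. The median size of the change was 0.31 and the largest 1.66 on the log2 scale. As the ratios may rest only on reads that could be placed at a single copy, they do not settle whether copy use differed.

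The share of the 10 most abundant entries differed between libraries more than between groups. Treatment stays open as a source, since the lowest share, 38.28%, was in a MesHMLE library and the other 2 MesHMLE libraries lay above both HMLE libraries, and the single low library is also the deepest. Saturation of deduplication, which may lower abundant entries in deep libraries, also stays open. For entries ranked 3 to 10 in a deep library of the other group, the log2 ratio of deep to shallow counts lay below that of entries ranked 51 to 150 by a median difference of -1.004 in MesHMLE (bootstrap 95% interval -2.61 to -0.465) and -0.51 in HMLE (-1.07 to 0.257), and the HMLE interval includes 0. A lower share of abundant entries in the deep library, from any cause, would give such a difference. The values therefore do not single out saturation. Differences between the cultures or in RNA recovery were not tested.

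More entries were called as fallen than as risen in MesHMLE. The choice among the scalings tried is argued against as the cause. At least 12 entries fell and at most 3 rose under each of RLE, upper-quartile, total-count scaling and scaling without the 10 most abundant entries. Under these the median log2 fold change of all entries ran only from -0.15 (RLE) to 0.02 (library totals). A larger shift common to all entries was not tested. A shift between deep and shallow libraries common to both groups is also argued against, since 11 of the 13 kept their call with depth as a block, where 13 fell and 2 rose. Over 20 thinnings to 120256 counts the median number of the 13 that kept their call was 9.5 (3 to 13), while their median log2 fold change was -4.84 (median SE 0.98) before and -5.05 (-5.54 to -4.44 over the thinnings, median SE 0.97) after, so the falls stayed about as large, and why calls ended was not tested. Of the 10 splits of the libraries into 2 and 3, only the real one (1 split) called as many as 15, and the highest other split, that by depth included, called 0, but 10 splits are too few for a share under 0.05. Every other split also puts treated and untreated libraries in the same group. Any real difference then widens the spread within groups, so the 0 calls do not settle whether the 15 could arise by chance.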
